A study of Mus musculus with 6 samples.

How the data were processed

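RNA was measured in dorsal root ganglion neurons of CD-1 mouse embryos at embryonic day 13, in 6 libraries. Of these, 3 came from neurons given a lentivirus with a control hairpin (shControl) and 3 from neurons given a lentivirus with a hairpin against Uhrf1 (shUHRF1). Per the labels' protocols, total RNA was extracted on columns with DNase digestion, ribosomal RNA was depleted, and cDNA was made with a SMARTer kit. The labels number the libraries 1 to 3 in each group and do not say whether they came from separate cultures. The p-values therefore measure the spread between these libraries, which may be technical.

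The authors deposited 1 table of whole-number read counts per library, with 47643 gene identifiers and 5 summary lines, and the values are raw counts. The submitters' processing notes list FastQC, STAR, HTSeq and DESeq2 and the mm10 build. Their versions, the annotation release and the strand setting are not given in the sources used here. Without the strand setting, reads of a gene and of an overlapping gene on the opposite strand cannot be told apart. The summary lines name no gene and were kept out of library sizes and tests. They held 8.43% to 17.18% of all entries as reads outside annotated genes, 2.12% to 2.27% as ambiguous, and 30.5% to 37.28% as not uniquely aligned.

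Gene symbols, coordinates and biotypes were taken from GENCODE release M21 on GRCm38, the assembly also called mm10. Of the identifiers, 47224 matched without their version suffix and 419 did not, and the latter held at most 0.04% of a library's counts. Exonic GC content and length were available for 99.1% of genes.

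From the deposited counts, differential expression was computed with edgeR 4.0.16 in R 4.3.3. Genes were filtered with filterByExpr at default settings, library sizes were scaled with TMM factors, and the quasi-likelihood F test compared the groups without a block. The test was two-sided with Benjamini-Hochberg adjustment, and genes with an adjusted p below 0.05 were called. CPM values were computed on the TMM-scaled library sizes. Standard errors of log2 fold changes were derived from the F statistic. Uhrf1 did not pass the filter, so its log2 fold change comes from the same fit with Uhrf1 kept. Counts were simulated from each gene's mean over all 6 libraries and from their library sizes, with 200 of 15573 genes changed. On these counts the fit recovered 14% of genes changed 1.5-fold, 38% at 2-fold, 82% at 4-fold and 98% at 8-fold. Of its 125 calls on these simulated data, 9 were false. In the real data 3735 genes were called, so neither the recovery nor the false calls carry over to that fit.

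The 27 gene lists, the rule for named genes and the alternatives were fixed before the data were examined. The rule always named a few genes, among them Uhrf1, Rest and Dnmt1. Some genes named by the rule are not reported here, and counts of list members include them. It added the 12 largest rises and the 12 largest falls among called genes with a mean of at least 5 CPM and no overlap between the groups, leaving out predicted, clone-named and mitochondrial genes. For each list it took up to 4 members with the smallest unadjusted p. Lists with at least 5 tested members were tested with camera from limma 3.58.1 at a preset correlation of 0.01, adjusted over the lists. Camera was also run with an estimated correlation, which left 0 lists called, and 0 at an unadjusted p below 0.05. The fry test, run on voom values, called 2. On simulated data, 2 of 200 unchanged lists reached a p below 0.05. Genes were drawn independently there, so this does not cover lists whose members move together.

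Libraries of the same replicate number deviated alike. Deviations from the group means correlated at 0.32, 0.40 and 0.40 between libraries of the same number and between -0.28 and 0 for other pairs across the groups. Deviations within a group sum to 0, so the values of the other pairs are not separate evidence. A pairing by number is inferred from the data, since the labels do not say what a number shares. A fit with the number as a block is given beside a result where it changed a call or moved a count by more than 1.5 times.

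The alternatives were DESeq2 1.42.0, limma-voom, RLE and upper-quartile factors, no low-count filter, a filter of at least 2 CPM in at least 3 libraries, the replicate block, removal of mitochondrial and small RNA genes, an offset for GC content and length, the block with that offset, other thresholds, and each library left out in turn. A fit on the library pairs numbered 1 and 3 was added after seeing the data, because the pair numbered 2 held the highest shares of reads outside annotated genes. For 7-base words in 3' UTRs, the fold change of 13168 genes with an annotated 3' UTR of at least 50 bases was regressed on the presence of each of 15858 words, with terms for 3' UTR length, GC content and abundance. As a check, a fall of 0.3 was planted for genes with a preset word, in the contrast of shControl replicate 1 with the other shControl libraries. Of the planted words, 4 of 4 ranked first. The planted fall was larger than the effect of -0.216 found for the top word, so recovery at that size was not tested. Python 3.11.15, numpy 2.4.6, pandas 2.3.3, scipy 1.17.1 and matplotlib 3.10.9 were used. Intervals on read counts cover counting error only.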

Results

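The question was how transcription in sensory neurons differs with a hairpin against Uhrf1. Total RNA was sequenced from embryonic mouse dorsal root ganglion neurons carrying a control hairpin or that hairpin, with 3 libraries in each group. UHRF1 binds hemimethylated DNA and recruits the maintenance methyltransferase DNMT1. The libraries held 15599776 to 22382813 reads in genes. Reads were found for 23310 to 24221 genes in shControl and for 25288 to 26115 genes in shUHRF1. The first principal component carried 60.5% of the variance and separated the groups. Correlations of log2 CPM were 0.9606 to 0.9879 within a group and 0.9281 to 0.9634 between groups, and no pair of libraries was close enough in counts to be 1 library deposited more than once.

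Uhrf1 itself (ENSMUSG00000001228.14, chromosome 17, 56303321 to 56323486, plus strand, GRCm38) was near the detection limit in every library. It had 8, 6 and 5 reads in the shControl libraries numbered 1, 2 and 3, and 2, 1 and 5 reads in the matching shUHRF1 libraries. Its mean was 0.364 ± 0.115 CPM (SD, n = 3) in shControl and 0.13 ± 0.098 CPM (SD, n = 3) in shUHRF1. The pooled ratio of 8 to 19 reads, scaled for depth, was 0.377, with a 95% exact Poisson interval of 0.143 to 0.901 that covers counting error only. Between libraries the decrease was not resolved. A two-sided exact permutation test gave p = 0.2, where 3 against 3 libraries allow no p below 0.1. The edgeR log2 fold change was -1.39 ± 0.62 (SE), with an adjusted p of 0.141, and -2.16 without shUHRF1 replicate 3. At this depth the libraries therefore give a knockdown estimate with a wide error.

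Rest (ENSMUSG00000029249.15, chromosome 5, 77265491 to 77286432), which encodes a repressor of neuronal genes, was higher in shUHRF1. Its level was 0.946 ± 0.266 CPM (SD, n = 3) in shControl and 5.19 ± 1.83 CPM (SD, n = 3) in shUHRF1, a log2 fold change of 2.45 ± 0.38 (SE) with an edgeR adjusted p of 0.00414. Every shUHRF1 library, at 6.6, 3.12 and 5.86 CPM, lay above every shControl library. In the same libraries the mean log2 CPM over 35 glial and fibroblast markers that passed the expression filter was 0.97, 1.02 and 1.19 in shControl. It was 2.19, 2.97 and 3.17 in shUHRF1. Dnmt1 had a log2 fold change of -0.31 ± 0.14 (SE) and did not pass (edgeR adjusted p = 0.156).

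**Figure D1:**
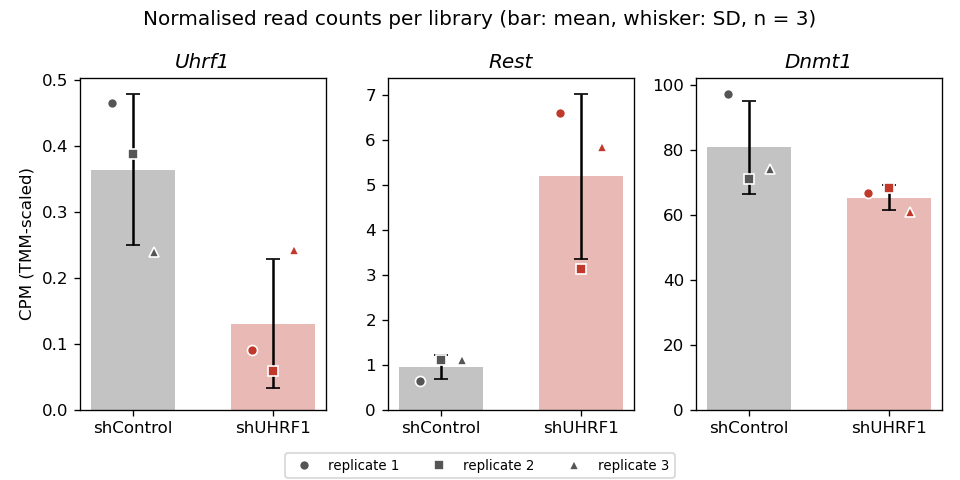
TMM-scaled CPM of Uhrf1, Rest and Dnmt1 in each library, with bars for the group mean and whiskers for the SD of 3 libraries. Rest lay at 3.12 to 6.6 CPM in the shUHRF1 libraries, above every shControl library, while the Uhrf1 values of the groups overlapped.

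Across the transcriptome, 3735 of 15573 tested genes (24%) differed between the groups by edgeR's test, 1807 higher and 1928 lower in shUHRF1. The large changes were mostly increases: 1098 genes rose and 655 fell at least 2-fold, and 442 rose and 88 fell at least 4-fold. Among 7983 genes at 16 CPM or more, 744 rose and 1586 fell, whereas among 7590 genes below this level 1063 rose and 342 fell. Of 347 tested lincRNAs, 52 rose and 10 fell. The groups did not overlap for 44% of tested genes, where chance gives 10%. With upper-quartile factors, which moved the median log2 fold change of all genes from 0.017 to 0.142, the split was 2512 higher and 1378 lower. The count was 2018 without shControl replicate 1, 1768 without shControl replicate 3 and 2171 without shUHRF1 replicate 3.

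The largest rises were led by Tac1, which encodes the precursor of substance P. It went from 1.94 ± 0.759 to 151 ± 114 CPM (SD, n = 3), a log2 fold change of 6.25 ± 0.65 (SE) with an edgeR adjusted p of 0.00109. Osmr, the oncostatin M receptor, rose by a log2 fold change of 5.23 ± 0.34 (SE). The collagen genes Col3a1 and Col1a2 rose by 4.35 ± 0.63 and 4.29 ± 0.37 (log2, SE), the matrix gene Postn by 4.30 ± 0.28, the laminin gene Lama4 by 4.16 ± 0.31, the nidogen gene Nid1 by 4.03 ± 0.22 and Sparc by 4.02 ± 0.37. Postn, Col1a2 and Col3a1 belong to the list of fibroblast markers, of which 10 of the 13 that passed the expression filter rose in the same libraries. Fignl2, Dnah6, Abca12 and Gucy1a1 completed the list, with log2 fold changes of 4.87, 4.77, 4.47 and 4.08. Without shUHRF1 replicate 1, where they were highest, Tac1, Fignl2, Dnah6 and Abca12 had log2 fold changes of 5.44, 4.25, 3.75 and 3.53 and still passed.

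Among the largest falls, Agpat1, an acyltransferase of phospholipid synthesis, went from 244 ± 46.2 to 14.1 ± 1.66 CPM (SD, n = 3), a log2 fold change of -4.12 ± 0.18 (SE) with an edgeR adjusted p of 0.000205. Timp2, an inhibitor of matrix metalloproteinases, went from 530 ± 105 to 46.9 ± 21.5 CPM (log2 fold change -3.50 ± 0.38, SE). The transcription factor gene Insm1, the neuropeptide gene Nmb, the calcium-binding protein gene Calb2 and the potassium channel gene Kcns1 had log2 fold changes of -4.08, -3.98, -3.59 and -3.19, and Insm1 had -4.81 without shUHRF1 replicate 2. Ptger4, Mesd, Thsd4, Cox14, Gna11 and Cyb5r3 had values of -3.28, -3.13, -3.08, -3.01, -2.92 and -2.91. Annotated exons of Nmb overlap those of Sec11a, and exons of Ptger4 overlap those of Ttc33 on the opposite strand, so these 2 values are uncertain.

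**Figure D2:**
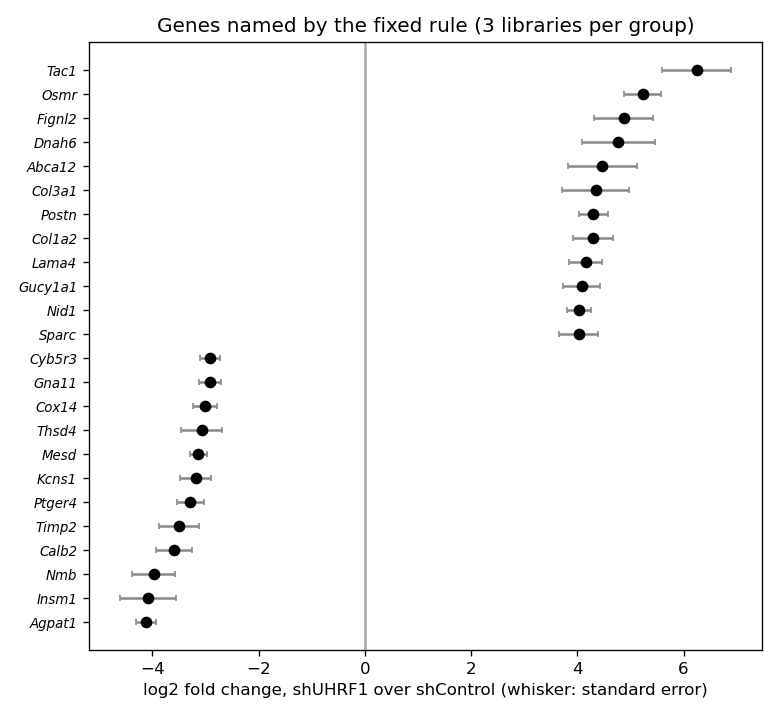
Log2 fold change of shUHRF1 over shControl for the 12 largest rises and 12 largest falls, with whiskers for the standard error (3 libraries per group). The values run from -4.12 for Agpat1 to 6.25 for Tac1.

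The neuropeptide, channel and subtype genes of sensory neurons were tested as a list, and 13 of 44 rose while 3 fell (camera adjusted p = 0.0223). The median log2 fold change was 0.16. Besides Tac1 and Osmr, the neuropeptide gene Adcyap1 rose from 13.5 to 53.7 CPM (log2 fold change 1.99 ± 0.15, SE) and Runx1, a transcription factor of nociceptors, from 2.02 to 21.3 CPM (3.40 ± 0.41). Among the falls, the potassium channel gene Kcnk18 went from 5.59 to 0.403 CPM (-3.81 ± 0.49). Markers of fibroblasts, glia and macrophages rose in the same libraries (10 of 13, 13 of 22 and 5 of 12 higher), shares that the expression filter leans toward rises. With the replicate block 14 of the sensory neuron genes rose and 6 fell, as they did adjusted over the list alone. The call was lost with an estimated correlation (adjusted p = 0.693), with limma-voom (adjusted p = 0.151), without shControl replicate 2 (adjusted p = 0.153) and without shUHRF1 replicate 2 (adjusted p = 0.102).

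Synaptic vesicle and release genes went the other way, with 17 of 48 lower and 3 higher in shUHRF1 (camera adjusted p = 0.01). Sncg fell from 1559 to 508 CPM, Vamp1 from 142 to 54.6 CPM and Nsf, an ATPase of vesicle fusion, from 383 to 179 CPM, whereas Dnm3 rose from 75.3 to 154 CPM. Adjusted over the list alone, 17 fell and 3 rose as well. In the same libraries 13 of 22 glial and 10 of 13 fibroblast markers rose, with median log2 fold changes of 2.46 and 3.30, and 3 of 24 neuronal markers fell. The expression filter leans the glial and fibroblast values toward rises, and the abundant glial markers S100b, Mbp and Cadm4 did not rise. The adjusted p was 0.81 with an estimated correlation and 0.0662 with the stricter filter. Of 50 axon guidance and adhesion genes, 15 fell and 4 rose (7 rose with the replicate block), a list that did not pass (camera adjusted p = 0.0913), and adjusted over the list alone 17 fell and 7 rose. The shUHRF1 libraries differed, with a mean log2(CPM + 1) of 5.189 in replicate 1, 5.751 in replicate 2, within the 5.638 to 5.837 of shControl, and 5.552 in replicate 3. Epha5 and the adhesion molecule gene L1cam fell by 1.29 and 0.87 on the log2 scale, while Robo2 and Itga6 rose by 1.09 and 2.91. With the offset for GC content and length this list passed, at an adjusted p of 0.042, as it did without shControl replicate 1 (0.0194), without shUHRF1 replicate 2 (0.0034) and with no low-count filter (0.00091).

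Genes tied to REST moved in both directions. Of 50 neuronal genes with a REST binding element, 13 fell and 7 rose, and the list did not pass (camera adjusted p = 0.274). Adjusted over the list alone, 13 fell and 8 rose. Olfm3 fell from 26.2 to 5.83 CPM and L1cam from 913 to 499 CPM, whereas the intermediate filament gene Ina rose from 121 to 427 CPM and Cacna1h from 74.8 to 158 CPM. Without a low-count filter this list passed, at an adjusted p of 0.042. Of 18 genes for REST and its corepressors, 3 rose and 3 fell, also adjusted over the list alone (camera adjusted p = 0.706). Rcor2 fell by 1.32 on the log2 scale.

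Growth-related lists did not pass as sets. Of 35 regeneration-associated genes, 5 rose and 7 fell, or 7 and 12 with the replicate block, and 5 and 8 adjusted over the list alone (camera adjusted p = 0.73). Gap43, a growth cone protein gene, fell from 1770 to 484 CPM (log2 fold change -1.87 ± 0.23, SE), while Adcyap1 and Junb rose, Junb from 3.5 to 13.4 CPM. Of 29 axon growth suppressors, 5 rose and 1 fell (1 fell and 4 rose adjusted over the list alone, 2 fell with the replicate block, camera adjusted p = 0.626). Socs3 rose from 0.44 to 1.96 CPM and Ptpn1 from 53.8 to 104 CPM, and Rhoa fell from 82.4 to 32.5 CPM.

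DNA methylation genes and the classes of genes that methylation silences did not pass as lists. Of 26 genes of the methylation machinery, 4 rose and 1 fell, also adjusted over the list alone, and 4 fell with the replicate block (camera adjusted p = 0.73). Tet2, a methylcytosine oxidase, rose from 30.1 to 77.8 CPM, Gadd45g from 3.66 to 9.88 CPM and Apobec1 from 0.289 to 1.59 CPM. Only 12 of 43 germline genes passed the expression filter, and 2 of them rose, Tex15 and Piwil2, by 1.03 and 0.97 on the log2 scale, with 3 higher under the replicate block (camera adjusted p = 0.576). Both lost their call without any 1 of shControl replicates 1, 2 and 3 and shUHRF1 replicates 1 and 3, with edgeR adjusted p from 0.0594 to 0.158, and on library pairs 1 and 3 alone (0.0663 and 0.1). Tex15 also lost it with no low-count filter (0.0604) and with the offset for GC content and length (0.061). Adjusted over the list alone, 0 germline genes were called, and 3 had an unadjusted edgeR p below 0.05. Imprinted genes went both ways, 6 up and 10 down of 39, or 6 and 12 adjusted over the list alone (camera adjusted p = 0.675). Zim1 rose from 15.3 to 125 CPM (log2 fold change 3.03 ± 0.20, SE), and Mest and Nnat fell by 1.56 and 1.52 on the log2 scale. Of 45 replication and cell cycle genes, 2 rose and 3 fell, with 5 lower under the replicate block (camera adjusted p = 0.466), and adjusted over the list alone 1 fell. Aurka fell from 3.98 to 0.956 CPM.

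Of 53 listed interferon-stimulated genes 29 were tested, of which 14 rose, 1 fell and 14 did not pass (camera adjusted p = 0.000226), with a median log2 fold change of 0.91. A gene near 0 in shControl passes the filter only when it is high in shUHRF1, so these values lean toward rises. The summed CPM of the tested genes overlapped, at 404.8 to 526.2 in shControl and 523.9 to 704.9 in shUHRF1. Their mean log2(CPM + 1) did not, at 2.8 to 3.032 and 3.428 to 3.594. Ifih1, a sensor of double-stranded RNA, rose from 0.297 to 3.47 CPM (3.52 ± 0.44, SE), Ifit1 from 0.714 to 6.5 CPM and Irf1 from 8.19 to 22.2 CPM. Adjusted over the list alone, 15 rose and 1 fell, and 3 fell with the replicate block. The adjusted p with an estimated correlation was 0.693, and markers of macrophages and fibroblasts moved in the same libraries.

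The lists of fibroblast, glial and macrophage markers were higher in shUHRF1, from a low base. Only 13 of 28 listed fibroblast, 12 of 22 macrophage, 11 of 24 endothelial and 5 of 20 muscle and cartilage markers passed the expression filter. A marker near 0 in shControl passes only when it is high in shUHRF1, so the shares and medians of tested markers lean toward rises. The camera p-values share this lean and are not error rates for the full lists. Of the tested fibroblast markers, 3 had at least 5 CPM in shControl. Of the 13 tested fibroblast and meningeal markers, 10 rose (camera adjusted p = 2.21e-08), with a median log2 fold change of 3.30. Postn, Col1a2 and Col3a1 led them, and Fap rose from 4 to 84 reads, whereas Thy1, the most abundant marker of this list and also a neuronal marker, had 320 CPM in shControl and 182 CPM in shUHRF1 (log2 fold change -0.82, edgeR adjusted p = 0.0783). In all, 10 rose and 1 fell adjusted over the list alone. Of 22 Schwann cell and satellite glia markers, 13 rose and 1 fell (camera adjusted p = 2.56e-05), with a median of 2.46. Erbb3 rose from 0.55 to 5.17 CPM, Fabp7 from 0.338 to 2.14 CPM and Kcnj10 from 0.159 to 1.65 CPM, whereas the abundant markers S100b, Mbp and Cadm4 had log2 fold changes of -0.54, -0.95 and -0.15. The counts were the same adjusted over the list alone. Summed over the tested members, glial markers had 753.8, 684.9 and 767.3 CPM in shControl and 301.1, 853 and 648 CPM in shUHRF1. Fibroblast markers, Thy1 included, had 416.6, 266.3 and 352 CPM in shControl and 208.4, 421.5 and 394.1 CPM in shUHRF1. Neither sum separated the groups, and the abundant members weigh most in these sums. Of 12 macrophage markers, 5 rose (camera adjusted p = 0.01), or 7 adjusted over the list alone. Among them Ptprc and Ctss had log2 fold changes of 4.26 and 3.55, and Ctss had 4.35 without shControl replicate 1 and 2.96 without shUHRF1 replicate 2. Of the most abundant macrophage markers, Lyz2 had 3.77 and kept its call in 3 of 6 fits with 1 library left out. Aif1 and C1qb had 0.71 and 0.35 and did not pass (edgeR adjusted p = 0.361 and 0.618). Of the 12 macrophage markers, 0 had at least 5 CPM in shControl. With an estimated correlation the adjusted p was 0.693 for fibroblast markers, 0.693 for glial markers and 0.81 for macrophage markers, and with the stricter filter it was 0.0662 for glial markers. Endothelial and mural markers did not pass (3 of 11 higher, 1 lower, camera adjusted p = 0.189), with 4 higher and 1 lower adjusted over the list alone. Eng and Pdgfrb rose, by 2.53 and 1.45 on the log2 scale, and Egfl7, the most abundant, had 35.2 CPM in shControl and 32.1 CPM in shUHRF1. The list passed with no low-count filter (0.0483). Muscle and cartilage markers did not pass either (2 of 5 higher, also adjusted over the list alone, and 3 with the replicate block, camera adjusted p = 0.279). Ttn rose from 3.35 to 27.1 CPM, a log2 fold change of 3.03, which was 2.21 without shUHRF1 replicate 1. Erythroid and neural tube lists had 4 and 2 tested members and were not tested as sets. Neither had a called member by edgeR, with 0 members at an unadjusted p below 0.05, and 1 erythroid gene was higher with the replicate block. Of 24 pan-neuronal and sensory neuron markers, 1 rose and 3 fell, also adjusted over the list alone, or 2 and 5 with the replicate block (camera adjusted p = 0.189). Gap43 fell, and Tubb3 fell from 5378 to 3201 CPM, a call lost with the offset for GC content and length (0.0579) and without shControl replicate 1 (0.0585), shControl replicate 3 (0.06) or shUHRF1 replicate 3 (0.0633). Prrxl1 rose and Neurod1 fell, with log2 fold changes of 1.31 and -1.01. They kept their calls in 3 and 2 of 6 fits with 1 library left out. The neuronal list passed without shControl replicate 2 (0.0476) and with no low-count filter (0.0122).

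**Figure D3:**
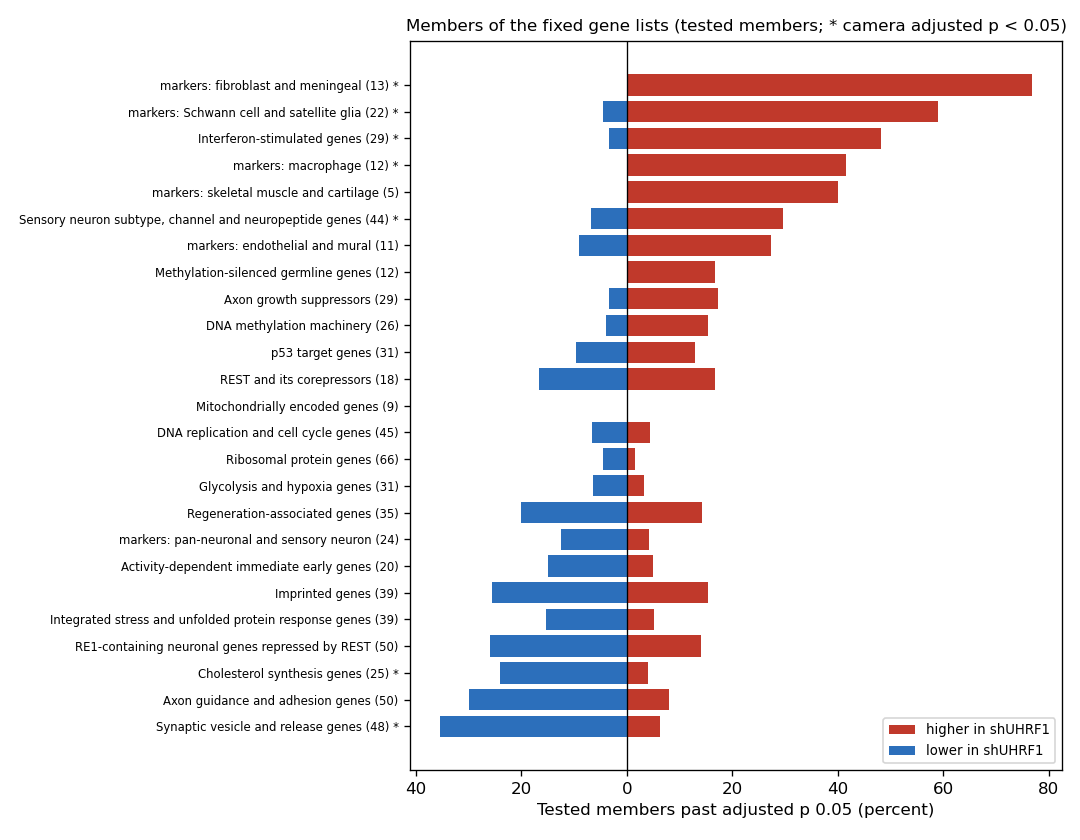
Percent of the tested members of each fixed list that passed an adjusted p of 0.05, higher (right) or lower (left) in shUHRF1, with tested members in parentheses and an asterisk where camera's adjusted p was below 0.05. Fibroblast markers lie at the top with 10 of 13 higher and synaptic vesicle genes at the bottom with 17 of 48 lower.

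On library pairs 1 and 3 alone, the calls for sensory subtype genes, cholesterol synthesis genes and macrophage markers were lost (camera adjusted p = 0.31, 0.327 and 0.106), and the lists of axon guidance genes and neuronal markers passed (0.0159 and 0.0337). By fry, which tests a list against no change and not against other genes as camera does, interferon-stimulated genes and muscle and cartilage markers passed (0.0377 each). The other lists that camera called did not pass by fry, with adjusted p of 0.053 for glial, 0.065 for fibroblast and 0.113 for macrophage markers, and 0.1 for sensory subtype, 0.113 for synaptic vesicle and 0.353 for cholesterol synthesis genes.

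Of 25 cholesterol synthesis genes, 6 fell, 1 rose and 18 did not pass (camera adjusted p = 0.0395), or 7 and 1 adjusted over the list alone and 9 down with the replicate block. Mvd and Stard4 fell by 1.12 and 1.06 on the log2 scale. In the same libraries 10 of 13 fibroblast, 13 of 22 glial and 5 of 12 macrophage markers rose, shares that the expression filter leans toward rises. The libraries of the group differed: the mean log2(CPM + 1) of the list was 7.602 in shUHRF1 replicate 1, above the 7.435 to 7.533 of the shControl libraries, and 6.873 and 7.055 in shUHRF1 replicates 2 and 3. This call was lost with an estimated correlation (adjusted p = 0.854), with the stricter filter (0.0958), without shControl replicate 2 (0.0512), without shUHRF1 replicate 2 (0.292) and without shUHRF1 replicate 3 (0.0864). Of 39 genes of the integrated stress and unfolded protein responses, 6 fell and 2 rose, also adjusted over the list alone, with 9 lower and 3 higher under the replicate block (camera adjusted p = 0.188). Atf5 fell from 152 to 38.2 CPM and Slc7a5 from 353 to 123 CPM, and Vldlr rose from 143 to 269 CPM. The list passed without shControl replicate 1 (0.0448), without shUHRF1 replicate 1 (0.023), without shUHRF1 replicate 3 (0.0233) and with no low-count filter (0.0097). Its mean log2(CPM + 1) was 5.026 in shUHRF1 replicate 2 alone, against 5.686 and 5.701 in shUHRF1 replicates 1 and 3, within the 5.615 to 5.828 of the shControl libraries. Glycolysis and hypoxia genes had 2 of 31 lower and 1 higher, or 7 and 2 with the replicate block (camera adjusted p = 0.274). None were called adjusted over the list alone, with 8 at an unadjusted edgeR p below 0.05, and the list passed without shUHRF1 replicate 3 at 0.00121, the library with the highest mean log2(CPM + 1) of this list (6.556, against 5.772 and 5.814 in shUHRF1 replicates 1 and 2 and 6.039 to 6.53 in shControl). The 9 mitochondrially encoded genes had 0 calls, and 0 at an unadjusted edgeR p below 0.05, with a median log2 fold change of 0.37. With the replicate block 4 of them were higher and the list passed (camera adjusted p = 0.0468), as it did without shControl replicate 1 (0.0443), but not with the block and the offset for GC content and length together (0.794) or with that offset alone (0.905). Of 31 p53 targets, 4 rose and 3 fell, also adjusted over the list alone, or 6 and 4 with the replicate block (camera adjusted p = 0.73), and Zmat3 fell from 85.9 to 35.1 CPM. The mean log2(CPM + 1) of these targets was 4.988 in shUHRF1 replicate 1, against 4.221 and 4.413 in shUHRF1 replicates 2 and 3 and 4.36 to 4.468 in shControl. Of 20 immediate early genes, 1 rose and 3 fell, also adjusted over the list alone, with 5 lower under the replicate block (camera adjusted p = 0.626), including Homer1, which fell from 46.2 to 24.8 CPM. Their mean was 2.521 in shUHRF1 replicate 2, against 3.126 and 3.05 in shUHRF1 replicates 1 and 3 and 2.867 to 3.137 in shControl. Of 66 ribosomal protein genes, 1 rose and 3 fell (camera adjusted p = 0.73), and adjusted over the list alone 0 were called, with 5 at an unadjusted edgeR p below 0.05.

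Fold changes depended on abundance. Across genes, which are not independent replicates, Spearman's rho of the log2 fold change was -0.285 with mean log2 CPM, -0.128 with exonic GC content and 0.033 with exonic length.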

Additional observations from a re-analysis of the deposited data

Results flagged for a closer look

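Tests of marker lists and of Rest against the markers were chosen after the results were seen, and the comparison of splits was not.

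Among genes below the expression filter, which were not among the 15573 genes tested, a mean of 9467 ± 88 (SD, n = 3) were detected per shUHRF1 library after thinning every library to the depth of the shallowest, against 7772 ± 675 (SD, n = 3) per shControl library. This is a signal outside the main measurement that lay above the control level. The share of unique reads outside annotated genes was also higher in shUHRF1 in each library pair, at 15.89% against 13.18%, 24.72% against 21.53% and 17.13% against 12.64%. Within shControl, replicate 2 had the highest such share and the most of these genes, 8532.

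The count of 3735 changed genes was set against the other splits of the 6 libraries. Of 10 splits, 1, the real one, gave as many, and the highest of the others gave 0 by edgeR, with 18 to 922 genes at an unadjusted p below 0.05. Of the 3 other splits that part all 3 library pairs, which mix the groups, each gave 0 with the replicate block, against 4820 for the real split. These 10 splits are too few for a share below 0.05.

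Rest and the lists of fibroblast, glial and macrophage markers were higher in the same libraries, although the abundant glial markers S100b, Mbp and Cadm4 did not rise. A lower share of neuronal RNA would raise markers of every other cell type alike only if neurons did not express them. The median log2 fold change of fibroblast markers exceeded that of endothelial and mural markers by 2.36 (two-sided permutation over markers, p = 0.00701, adjusted p = 0.0421 over 6 pairs of lists). The other 5 pairs of glial, fibroblast, macrophage and endothelial lists did not pass (adjusted p from 0.443 to 0.451). The pair that passed cannot decide on this explanation, since a marker that neurons also express would rise less. Egfl7 of the endothelial list had 35.2 CPM in shControl and 32.1 CPM in shUHRF1. The adjusted p was near the threshold, the markers are not independent, and the endothelial list itself passed with no low-count filter (0.0483). More RNA of glia and fibroblasts in the shUHRF1 libraries could not be separated from a change of Rest within neurons: relative to the glial and fibroblast markers, Rest was 0.58 ± 0.57 (SE, 3 libraries per group) higher on the log2 scale. Of these 35 markers, 11 had at least 5 CPM in shControl, and the neurons themselves may express them. A marker near 0 in shControl passes the filter only when it is high in shUHRF1, so the relative rise of Rest leans low. Within shUHRF1, Rest was highest in replicate 1 (log2 CPM 2.75), where the marker mean was lowest (2.19). It was 1.69 with a marker mean of 2.97 in replicate 2, and 2.58 with 3.17 in replicate 3. Loss of UHRF1 as a cause of the rise in Rest stays open.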

How the results depend on the processing

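The fit on library pairs 1 and 3 was chosen after seeing the data. Counts of changed genes stayed within 1.5 times of 3735 in the settings with all 6 libraries, from 2982 at 1.5-fold or more to 5193 at an adjusted p below 0.10, with 4820 under the replicate block. Library pairs 1 and 3 alone gave 3071. Leaving out 1 library gave 1768 to 3888 genes, 822 to 1814 higher and 946 to 2074 lower, with fewer samples. Of the 3735 genes, DESeq2 called 3611, the block 3709 and the GC and length offset 3442 in the same direction, and 0 were called in the opposite direction under any setting. The Uhrf1 log2 fold change stayed negative and did not pass in any setting, from -2.16 to -1.12 with 1 library left out. Rest passed in all settings (2.21 to 2.68 with 1 library left out). Over Dnmt1 and the 24 genes named by size, 425 of 425 alternative values kept their side of the threshold. Over 91 list members, 1347 of 1522 values did, 156 lost and 19 gained a call, and no called value changed sign. List calls were less stable: 7 lists were called, 8 with the replicate block, 12 without a low-count filter, 3 with the stricter filter, 0 with an estimated correlation, and 6 to 10 with 1 library left out. Fry, which tests against no change and not against other genes, called 2 lists, 1 of them among the 7. The filters change which genes are tested; the cause was not tested for the rest. Of the single list tests, fry included, 402 stayed on their side of the threshold, 25 lost and 19 gained a call. Apart from the mitochondrially encoded list, the block changed no other call among the lists and the genes named by size. Depth limits Uhrf1, at 1 to 8 reads per library.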

Other observations

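The tests of gene families and of overlapping words in Uhrf1 were chosen after the results were seen. Gene families, taken by symbol, added detail on the matrix and on membrane traffic. Of 32 collagen genes, 16 rose and none fell (camera adjusted p = 5.29e-08 over 20 families), with a median log2 fold change of 1.28. Fibroblast markers (10 of 13 higher, median 3.30) and glial markers (13 of 22 higher) moved in the same libraries, and Col1a2 and Col3a1 are in both the family and the fibroblast list. The expression filter leans these marker values toward rises. Col25a1, a collagen of neurons, was already abundant and rose from 183 to 440 CPM, and Col18a1 rose from 5.29 to 21.3 CPM. Of 9 laminin genes, 5 rose, among them Lamc1 from 26.8 to 48.8 CPM and Lama2 from 0.361 to 3.19 CPM (camera adjusted p = 0.00098). Of 51 Rab GTPase genes, which direct vesicle traffic, 14 fell and 2 rose (camera adjusted p = 0.000822). With an estimated correlation the adjusted p was 0.563 for each of these 3 families.

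A short word in 3' UTRs was more frequent among genes lower in shUHRF1, although most of these lack it. The word CAGTGCC ranked first of 15858 words, with t = -11.85 across genes and a Bonferroni-adjusted p of 5.13e-28. The lowest t of any word in 6 contrasts within a group was -6.29. These contrasts had 0 to 9 words past the same Bonferroni threshold, and genes are not independent, so this p is not a calibrated error rate. Between the groups 22 words passed this threshold on the lower side and 3 on the higher side. The 2117 genes with the word had a median log2 fold change of -0.17 against 0.02 for 11051 without it. Of genes with no copy 12.1% were called lower, with 1 copy 23.2%, and with 2 or more copies 34.2%. The word ranked first in each library pair, with t of -12.2, -10.0 and -11.13, and 4 of the 12 largest falls (Timp2, Mesd, Thsd4 and Gna11) and 1 of the 12 largest rises (Nid1) hold it, against 2117 of all 13168 genes searched. This pattern is consistent with a short RNA in the shUHRF1 libraries that pairs with the word by its seed. It does not cover the 1338 genes called lower without the word.

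A candidate source of such a short RNA is the hairpin against Uhrf1, whose sequence was not analysed here. Of 7 annotated Uhrf1 transcripts, 4 hold CAGTGCC, at chromosome 17, 56310783 to 56310789 on GRCm38, in coding exon 4 of 17 of the longest transcript, within CCTGTAGCTCCAGTGCCGTTAAGACCT. This is weak evidence, since 38.8% of 4652 coding transcripts of similar length (3227 to 3945 bases) hold the word as well. A sum of t over 3 overlapping words also counts other extensions of CAGTGCC, so it cannot decide on a longer match. The lowest such sum in Uhrf1 was reached by 19.58% of these transcripts. The 9-base word behind that sum, CAGTGCCGT, is in 1.03% of them, but it was picked after it had been seen in Uhrf1. The scan of all words did not use Uhrf1, and there GTGCCGT had rank 3 (t = -7.55) and AGTGCCG rank 13 (t = -5.56). Words with other extensions, AGTGCCA and AGTGCCT, had ranks 2 and 4 (t = -10.13 and -7.37). An endogenous microRNA with a seed for CAGTGCC that rises in shUHRF1 was not tested.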
